A study of Homo sapiens with 6 samples.

How the data were processed

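The series holds 6 total RNA libraries from human adipose tissue. Cells of the vessel adventitia, the outer coat of blood vessels, carried CD34 and lacked CD31 and CD45, and were sorted by fluorescence into a fraction with high and a fraction with low surface CD201, with 3 libraries each. The labels state this gate in 2 ways, since the protocol text also excludes cells with CD146, encoded by MCAM, while its antibodies and the design text do not mention CD146. CD201 is the endothelial protein C receptor, encoded by PROCR. The labels call the 3 libraries of a class biologic replicates and do not say whether they come from separate donors, so p-values here measure the spread between these samples, which may in part be technical. The libraries were stranded and read from 1 end, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, Partek and the genome build GRCh38.p13. The aligner and the counting rule are not given in the sources used here.

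The authors deposited 1 table of 16914 genes by 6 columns on a log2 scale. Its name speaks of RefSeq 99, a minimum of 10 of an unnamed quantity, FPKM, a pad of 1 and a logarithm with quantile normalization. The columns are named Pos and Neg with numbers 1 to 3, which were read as CD201High and CD201Low with the same numbers, and the PROCR values given in the report bear on that reading. The 6 columns share nearly 1 set of sorted values, with a maximum of 19.4 in each, which fits the quantile step. The base of the logarithm and the pad were read from the low values. In each library many genes share the same low value, up to 160 to 204 genes at 1 value, and the values shared by at least 25 genes form steps. Steps 8 to 16 lay on average 0.09 from log2(step + 1), against 1.06 for the natural logarithm and 2.50 for base 10, with a largest distance of 0.31 from log2(step + 1). At these steps the deposited values thus resemble whole reads plus 1 on a log2 scale without division by gene length. Across 11893 genes with a mean above 4 the Pearson r of the mean value with log2 transcript length was −0.07 (across genes, which are not independent replicates). Values with or without division by length could give such an r, so it does not decide between them. The absolute scale is therefore unclear, and only differences between libraries are interpreted. The quantile step gives each library the same total, so the depth of a library is unknown and no count test was run.

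Exact 0 values are a further limit. The libraries list 998, 1098 and 1615 genes at 0 in CD201High replicates 1, 2 and 3, and 1058, 998 and 998 in CD201Low replicates 1, 2 and 3. In CD201High replicate 3, 426 genes are at 0 that are above 0 in the other 5 libraries, against 70 to 123 in each other library, and 2 of the 426 are above 6 in each of the other 5. The smallest value above 0 was 1.63 in CD201High replicate 3, against 0.00455 to 0.314 in the other libraries. A 0 thus need not mean that the transcript is absent. Whether it is a failed estimate or reflects low depth was not tested. For genes with a 0 each library's value is given, and no fold is given against a group in which all libraries are at 0.

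XIST, TSIX and genes found only on chromosome Y were left out, 3 genes in all, which left 16911 genes. No symbol had several rows. Of the 16911 symbols, 16433 matched the gene name tables used here. The groups were compared with the moderated linear model of limma 3.58.1 in R 4.3.3, with a trend of the prior variance on the mean value and group as the only term, two-sided, and Benjamini-Hochberg adjusted p-values over all genes tested. A gene was called at an adjusted p under 0.05. A second count takes genes with an unadjusted p under 0.05 and a difference of at least 1 on the log2 scale, which is 2-fold. Differences are CD201High minus CD201Low and lie on the log2(value + 1) scale, which understates the change of low genes. The pipeline was tested on simulated data of the same 16911 genes, in which it recovered 18%, 56%, 78% and 88% of 50 genes each with a log2 difference of 0.5, 1, 2 and 3, with 4 false calls among 128. The changed genes were drawn from those with a mean above 4, and the noise was normal and independent between genes. No simulated library stood apart and no genes moved together, so these shares need not hold for the data.

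Before the data were examined, 44 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 5 genes in the table, 41 of the 44, were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way or, in its mixed form, in either direction, were run beside it. Some genes belong to more than 1 list, so lists that share genes are not separate findings. Among members of the DPP4-positive adventitial progenitor list, CD55 is also in the complement list and SEMA3C among the angiogenic factors. Named genes are the sort markers, the 10 genes with the largest and the 10 with the smallest difference among called genes without overlap between groups and with a mean of at least 1 in the higher group, up to 4 members with the smallest p of each list described, and the most abundant member of each list of another cell type. Symbols of non-coding or uncharacterised loci and of pseudogenes were skipped among the largest and smallest differences. Among the 10 genes with the smallest difference 1 is not reported here, nor is 1 of the lists, so the genes given are not the full set and their order is not a ranking. Erythroid and platelet lists had 3 genes each in the table and the mitochondrially encoded list had 0, so these lists were not tested. Positions are from GENCODE release 29 on GRCh38, and are those of the whole gene.

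Alternatives were a replicate block, other normalizations, pseudocounts of 0.1 and 5, filters at a mean of at least 1 and at least 3, other variance models, library weights, and leaving out each library or both libraries of 1 number. Testing all rows separately had nothing to change, since no symbol was repeated. An alternative on genes above 0 in all 6 libraries was chosen after seeing the data.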

Results

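Gene expression was measured in CD34-positive adventitial cells of human adipose tissue that were sorted by the level of CD201 on their surface, with 3 CD201High and 3 CD201Low libraries. The design asks how adventitial cells with much CD201 differ from those with little. The depth of each library is unknown, and values are on a log2 scale with a pad of 1. Within groups the median SD over the 8531 genes with a mean of at least 8 was 0.162 in CD201High and 0.131 in CD201Low. On the first principal component of these genes, which held 45.9% of the variance, the CD201Low libraries lay between 10.96 and 15.05 and the CD201High libraries at −6.31, −7.20 and −25.3. CD201High replicate 3 thus stood apart from its group, and it also lay at −14.1 on the second component, where the other CD201High libraries lay at 11.7 and 15.2.

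PROCR, the gene that encodes CD201, lay at 12.30 ± 0.05 (SD, n = 3) in CD201High and 10.43 ± 0.12 (SD, n = 3) in CD201Low cells, a log2 difference of 1.87 (SE 0.09, limma adjusted p = 1.68e-07), or 3.65-fold. The gene lies on chromosome 20 from 35172073 to 35216240. Every CD201High library was above every CD201Low library. The exact permutation test of the difference gave p = 0.1, two-sided, the smallest that 3 against 3 allows. CD34, on which all cells were selected, was at 14.64 ± 0.05 and 14.43 ± 0.04 (SD, n = 3 each), with a limma adjusted p of 0.0624. PTPRC, which encodes CD45, was listed at 0, 2.92 and 0 in CD201High and at 1.24, 0 and 0 in CD201Low replicates 1, 2 and 3. PECAM1, which encodes CD31, was at 5.66, 3.98 and 0 in CD201High and at 5.45, 5.69 and 4.61 in CD201Low, and MCAM, which encodes CD146, at 5.27 ± 0.78 and 5.45 ± 0.26 (SD, n = 3 each). The list of the 5 sort markers was called higher by camera (adjusted p = 0.0311, and adjusted p = 0.216 with an estimated correlation), with 1 member past the test over all genes and 2 higher when adjusted over the list alone. That 1 member is PROCR, which the sort itself sets apart, and the list was not tested without it. The list lost the call without CD201High replicate 1 (0.14), 2 (0.102) or 3 (0.0568) and without CD201Low replicate 3 (0.0551).

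CD201High cells had more transcript of genes known from the DPP4-positive progenitors of the adventitia, and CD201Low cells had more transcript of genes known from committed preadipocytes, among them genes for fatty acid uptake and lipid storage. Between the groups 571 of 16911 genes passed, 301 higher and 270 lower in CD201High (limma, adjusted p under 0.05), and all 571 had no overlap between groups. Without overlap were 3191 of all genes, or 18.9%, where chance gives 10%. At an unadjusted p under 0.05 there were 2295 genes, 1135 higher and 1160 lower, and 697 of these, 371 higher and 326 lower, also differed at least 2-fold. Among the called genes 136 higher and 65 lower ones differed at least 2-fold, and 23 higher and 10 lower ones had at least 1 library at 0. The count fell to 208, 193 and 347 without CD201High replicate 1, 2 or 3, and to 182, 196 and 273 without CD201Low replicate 1, 2 or 3. It was 118 with no variance trend, 131 with no variance moderation and 963 with library weights.

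**Figure D1:**
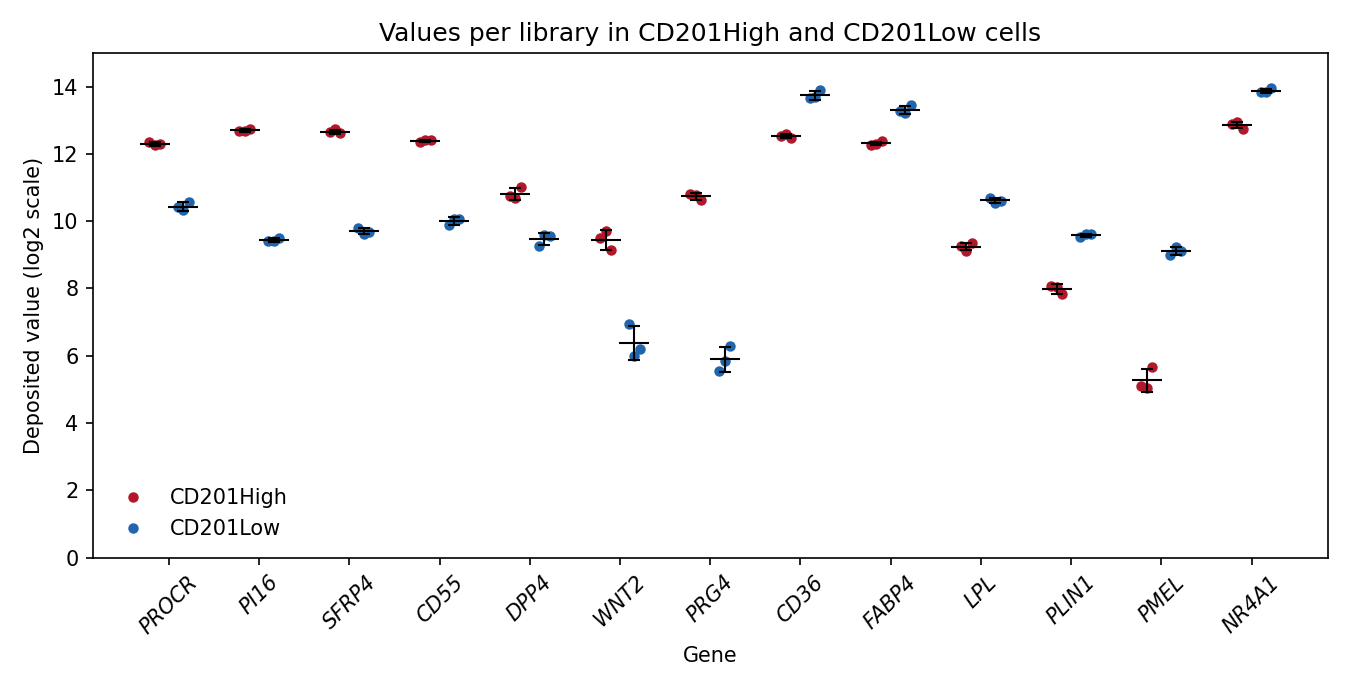
Deposited values on the log2 scale (y axis) of 13 genes (x axis) in each CD201High (red) and CD201Low (blue) library; black marks are the mean and SD of 3 libraries. PROCR, PI16, SFRP4, CD55, DPP4, WNT2 and PRG4 lay higher in every CD201High library than in any CD201Low library, and CD36, FABP4, LPL, PLIN1, PMEL and NR4A1 lay lower.

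Genes of the DPP4-positive adventitial progenitor, a stem-like fibroblast described in adipose and other tissues, were higher in CD201High cells. Of its 31 measured members, 21 rose, 0 fell and 10 did not pass, and when adjusted over the list alone 25 were higher and 1 lower. PI16, a secreted peptidase inhibitor that marks these cells, was at 12.71 ± 0.04 against 9.43 ± 0.05 (SD, n = 3 each), 9.67-fold higher (limma adjusted p = 1.01e-09). It lies on chromosome 6 from 36948263 to 36964837. SFRP4, a secreted Wnt antagonist, was 7.82-fold higher, CD55, which protects cells from complement, 5.24-fold higher, and MFAP5, a component of elastic microfibrils, 2.79-fold higher. These 4 genes passed with any 1 library left out. Camera called the list higher (adjusted p = 2.88e-43), and it held with an estimated correlation (adjusted p = 0.0125). The number of members that rose was 16 to 20 with 1 library left out.

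Genes of the committed preadipocyte were lower in CD201High cells. Of 26 members 16 fell, 2 rose and 8 did not pass, and 19 were lower and 4 higher when adjusted over the list alone. CD36, a fatty acid transporter, was at 12.54 ± 0.07 in CD201High and 13.74 ± 0.14 in CD201Low (SD, n = 3 each), a log2 difference of −1.21 (limma adjusted p = 3.27e-06). FABP4, a fatty acid carrier on chromosome 8 from 81478419 to 81483263, was at 12.31 ± 0.06 and 13.31 ± 0.12. LPL, which releases fatty acids from lipoproteins, differed by −1.37 and PLIN2, which coats lipid droplets, by −0.86. These 4 genes passed with any 1 library left out. Camera called the list lower (adjusted p = 3.76e-16, and adjusted p = 0.0217 with an estimated correlation). Fewer members fell without CD201High replicate 1 or 2 (8 each), without CD201Low replicate 1 (7) and without CD201Low replicate 2 or 3 (8 each), and 11 fell without CD201High replicate 3, while 0 or 1 rose with any 1 library left out.

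Mature adipocyte genes were lower as a list. Of 16 members 6 fell, 0 rose and 10 did not pass, with 7 lower when adjusted over the list alone, and camera called the list lower (adjusted p = 1.75e-11, and adjusted p = 0.0263 with an estimated correlation). PLIN1, which coats lipid droplets in fat cells, differed by −1.60 (7.99 ± 0.14 against 9.59 ± 0.04, SD, n = 3 each), CIDEC, which fuses lipid droplets, by −0.99, and GPD1, which makes glycerol phosphate and is the most abundant member, by −0.77. ACACB, a carboxylase that makes malonyl-CoA, was at 10.38 ± 0.05 and 11.38 ± 0.23 (SD, n = 3 each). These 4 genes passed with any 1 library left out. ADIPOQ, which encodes the adipocyte hormone adiponectin, did not pass, with 1.77, 6.31 and 7.43 in CD201High and 5.53, 6.76 and 7.17 in CD201Low replicates 1, 2 and 3. LEP was listed at 0 in every CD201High library and at 0, 3.77 and 0.97 in CD201Low.

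Of 27 elastic fibre and small proteoglycan genes 11 rose, 1 fell and 15 did not pass, with 12 higher and 5 lower when adjusted over the list alone. FBN1, the main microfibril protein, was 2.63-fold higher, LOXL1, which cross-links elastin, 2.19-fold and VCAN, a large proteoglycan, 2.20-fold. Camera called the list higher (adjusted p = 1.85e-07, and adjusted p = 0.0404 with an estimated correlation). Fewer members rose without CD201High replicate 1 or 2 and without CD201Low replicate 2 (7 each), and 0 or 1 fell with 1 library left out. FBN1 and MFAP5, which rose, are also members of the DPP4-positive adventitial progenitor list. The basement membrane list went the other way. Of 21 members 5 fell, 0 rose and 16 did not pass, with 13 lower when adjusted over the list alone. COL15A1 differed by −0.82, NID1 by −0.38, COL4A2 by −0.61 and COL4A1 by −0.59. Camera called it lower (adjusted p = 1.01e-06, and adjusted p = 0.265 with an estimated correlation). With any 1 library left out other than CD201Low replicate 3 the number that fell was 1, and without that library it was 7. NID1, COL4A1 and COL4A2 each passed with 1 of the 6 libraries left out and not with the others, and their adjusted p was highest without CD201Low replicate 1, at 0.12, 0.318 and 0.301. COL15A1 passed with any 1 library left out and is also in the committed preadipocyte list, as is HSPG2.

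The protein C and coagulation list, which holds PROCR itself, had 5 of 15 members higher, 1 lower and 9 not past the test, with 7 higher and 2 lower when adjusted over the list alone. THBD, which encodes thrombomodulin, a cofactor in the activation of protein C, was 3.48-fold higher (10.10 ± 0.30 against 8.29 ± 0.11, SD, n = 3 each) and F10, coagulation factor X, 1.83-fold higher, while GAS6, a ligand of TAM receptors, differed by −0.51. Camera called the list higher (adjusted p = 5.34e-06, and adjusted p = 0.0432 with an estimated correlation). PROCR, which the sort itself sets apart, is among the 5 that rose, and the list was not tested without it. The number that rose was 3 without CD201High replicate 1 or 2 and without CD201Low replicate 1.

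Immediate early genes, which respond within minutes to stimulation or tissue dissociation, were lower as a list in CD201High cells. Of 30 members 11 fell, 1 rose and 18 did not pass, with 16 lower and 1 higher when adjusted over the list alone, and camera called the list lower (adjusted p = 8.92e-12, and adjusted p = 0.0263 with an estimated correlation). NR4A1 and NR4A2, nuclear receptors of this class, differed by −1.02 and −1.16, MAFF by −0.58 and FOSB by −0.56. NR4A1, NR4A2 and MAFF passed with any 1 library left out, while FOSB had an adjusted p of 0.0695 without CD201High replicate 2. The number that fell was 5 and 3 without CD201High replicate 1 and 2, and 4 and 6 without CD201Low replicate 1 and 2. In the heat shock and protein folding list 0 of 21 members passed by limma, with 2 lower at an unadjusted p under 0.05, and the median difference was −0.04 (camera adjusted p = 0.267).

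**Figure D2:**
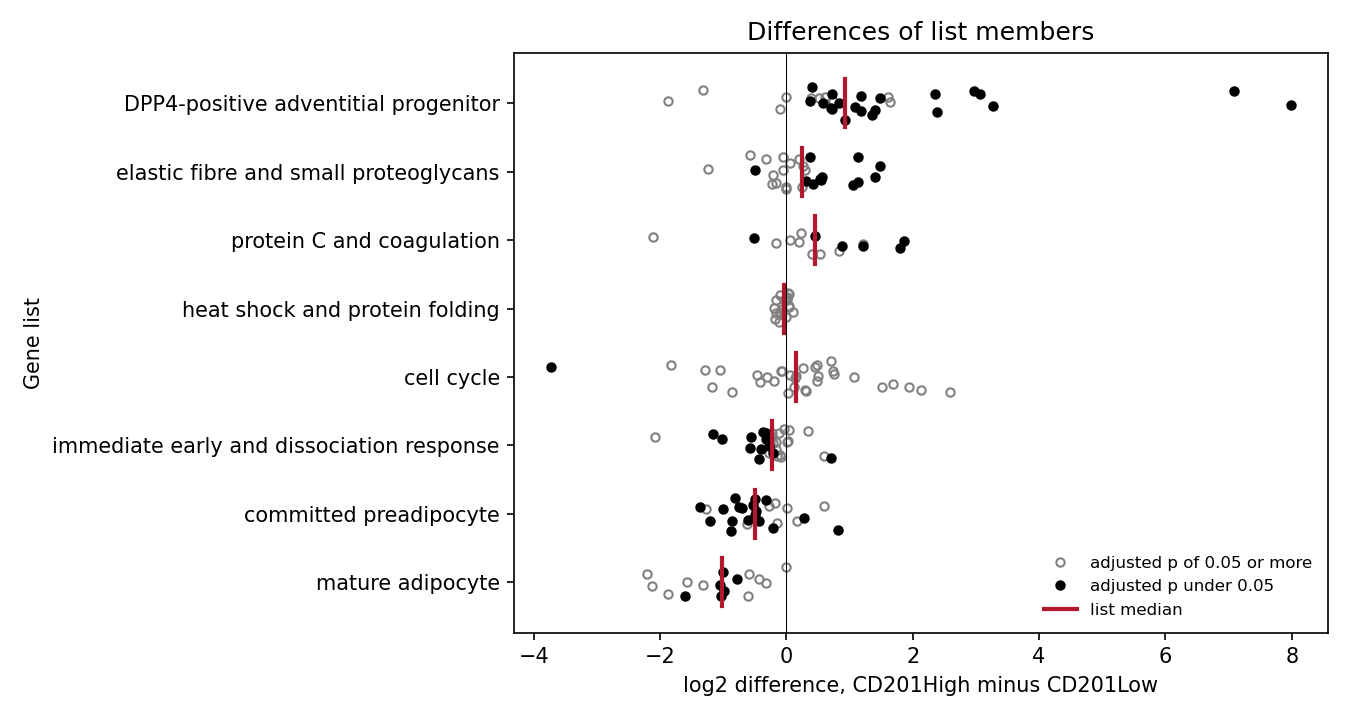
Log2 difference, CD201High minus CD201Low (x axis), of the members of 8 gene lists (y axis); each point is a gene, filled where its limma adjusted p is under 0.05, and the red bar is the list median. Medians were 0.92 for the DPP4-positive adventitial progenitor list, −0.49 for committed preadipocyte genes, −1.02 for mature adipocyte genes and −0.22 for immediate early genes.

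The genes with the largest differences were low, or listed at 0, in CD201Low libraries. DACT2, an intracellular regulator of Wnt and TGF-beta signalling, was at 8.95, 9.03 and 9.19 in CD201High and listed at 0, 0 and 3.23 in CD201Low, and BMP7, a growth factor, at 7.53, 7.96 and 7.49 against 1.74, 0 and 0. MYO5B, a myosin motor, was at 7.11, 7.18 and 6.52 against 0, 0 and 0.66, ADGRG2, an adhesion receptor, at 7.51, 6.94 and 7.87 against 0.56, 2.67 and 0, and CD70, a TNF family ligand, at 6.61, 6.68 and 6.70 against 0, 0 and 2.07. The Wnt ligand WNT10B was at 9.05 ± 0.12 against 3.39 ± 1.43 (SD, n = 3 each). PRG4, which encodes lubricin and lies on chromosome 1 from 186296279 to 186314562, was at 10.74 ± 0.10 against 5.89 ± 0.38 (SD, n = 3 each), 28.9-fold higher (limma adjusted p = 1.06e-07). These 7 genes passed with any 1 library left out. WNT4 (6.74, 6.08 and 5.35 against 0.56, 2.67 and 0), TEK (6.38, 4.48 and 4.97) and SCUBE1 (5.48, 3.88 and 6.37) also passed, the last 2 listed at 0 in all CD201Low libraries. Of the 6 fits with 1 library left out, WNT4 passed in 1, TEK in 4 and SCUBE1 in 2. Their highest adjusted p was 0.11 without CD201High replicate 2 for WNT4, and without CD201High replicate 1 it was 0.0525 for TEK and 0.0748 for SCUBE1.

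In the other direction PMEL, best known as a protein of pigment cell organelles, was at 5.27 ± 0.35 in CD201High and 9.11 ± 0.12 in CD201Low (SD, n = 3 each), 14.4-fold lower in CD201High (limma adjusted p = 1.05e-05). It lies on chromosome 12 from 55954105 to 55973317. It passed with any 1 library left out. Another 8 genes did not. ABCD2, a peroxisomal fatty acid transporter, was at 0.33, 1.73 and 2.64 against 6.29, 6.40 and 6.26, CLDN5, a tight junction protein of endothelium, at 4.69, 2.86 and 0 against 6.49, 6.49 and 6.42, and PCDHGB3, a protocadherin that shares exons with its cluster and is uncertain for that reason, at 0.05, 0 and 1.76 against 6.19, 3.85 and 4.57. CD300LG (4.49, 5.04 and 5.02), RBP7 (4.42, 4.69 and 4.55), RPS6KA6 (5.09, 3.04 and 5.35), GPRIN3 (2.67, 4.49 and 4.88) and PLK1 (4.07, 3.55 and 3.55) were above 0 in CD201Low and listed at 0 in all CD201High libraries. Of the 6 fits with 1 library left out, CD300LG passed in 5, RBP7 in 3, ABCD2 in 2, PLK1 and RPS6KA6 in 1, and CLDN5, GPRIN3 and PCDHGB3 in 0. Their adjusted p was highest without CD201Low replicate 1, where it was 0.0803 for ABCD2, 0.345 for CLDN5, 0.196 for PCDHGB3 and 0.148 for RPS6KA6, or without CD201Low replicate 2, where it was 0.0661 for CD300LG, 0.078 for RBP7, 0.223 for GPRIN3 and 0.153 for PLK1.

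Of the lists of other cell types that could be tested, camera called mature adipocyte genes and no other. In the endothelial list 2 of 21 members rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.994). AQP1, a water channel, was at 10.78 ± 0.08 against 9.11 ± 0.19 (SD, n = 3 each) and TEK also rose, while CLDN5 fell and CDH5, the cadherin of endothelium, was at 4.73 ± 1.44 against 7.34 ± 0.91 (SD, n = 3 each), with a limma adjusted p of 0.0665. With 1 library left out 1 or 2 of the list rose and 0 fell. PECAM1, given above, was also lower in mean in CD201High (limma adjusted p = 0.501), while 9 of the 21 members were higher in mean. Since the members went both ways, the lack of a camera call does not show that endothelial content was equal. The most abundant member, RAMP2, was at 11.17 ± 0.04 and 11.36 ± 0.14. In the pericyte and smooth muscle list 1 of 20 fell, MYLK (−0.84, and adjusted p = 0.11 without CD201High replicate 2), 0 rose (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.875), and the most abundant member, CALD1, was at 13.29 ± 0.05 and 13.35 ± 0.06. Of the macrophage and monocyte list 0 of 18 passed by limma, with 2 higher and 1 lower at an unadjusted p under 0.05 and adjusted over the list alone (camera adjusted p = 0.0668, 0.00993 without CD201High replicate 3 and 0.0366 without CD201Low replicate 2). The list lay toward CD201High, with a median difference of 0.79, 14 of 18 members higher in mean and a fry adjusted p of 0.0488. With an estimated correlation its camera adjusted p was 0.282. ITGAX was at 3.89, 3.65 and 2.36 in CD201High and listed at 0 in all CD201Low libraries, with a limma adjusted p of 0.104, and CD68, the most abundant member, was at 11.22 ± 0.16 and 11.37 ± 0.09. CD74 was higher in mean, at 8.56 ± 0.14 against 7.93 ± 0.08, and CD14 lower, at 9.44 ± 0.17 against 9.98 ± 0.29 (SD, n = 3 each). Both had a limma adjusted p of 0.109. For lymphocytes and mast cells 0 of 11 passed by limma, with 0 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.952), and KIT was at 4.04, 6.17 and 0 against 5.63, 7.16 and 6.69. Of 12 Schwann cell and nerve genes 0 passed by limma and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.658), with PMP22 at 13.81 ± 0.08 and 13.79 ± 0.11. PRG4 was the only one of 6 mesothelial genes to pass (camera adjusted p = 0.552). Of 3 genes of the platelet list GNG11 fell (−0.36, and adjusted p = 0.246 without CD201Low replicate 1). GNG11 lay at 11.28 ± 0.08 and 11.64 ± 0.11 (SD, n = 3 each), far above GP1BA and ITGA2B, which were listed at 0 in at least 1 library. Its fall thus need not reflect platelets. Of 3 erythroid genes 0 passed by limma and 1 was lower at an unadjusted p under 0.05 and over the list alone, with HBA2 at 7.18 ± 0.53 and 7.69 ± 0.37.

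Wnt pathway genes went both ways. Of 34 members 6 rose and 3 fell, with 7 higher and 7 lower when adjusted over the list alone, and camera made no call (adjusted p = 0.662). Fry, in contrast, called the list higher (adjusted p = 0.0295). With 1 library left out 5 or 6 rose and 0 or 1 fell. The ligand WNT2 was 8.36-fold higher (9.44 ± 0.29 against 6.38 ± 0.50, SD, n = 3 each), the secreted Wnt modulator DKK3 3.32-fold higher, and SFRP4 and DACT2 rose as given above. WNT2, SFRP4 and DACT2 are also in the DPP4-positive adventitial progenitor list. Of 39 TGF-beta and BMP genes 4 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.53), among them LTBP4, which binds latent TGF-beta (15.13 ± 0.23 against 13.91 ± 0.20, SD, n = 3 each), and INHBB, an activin subunit, which differed by −1.18. With 1 library left out 2 or 3 of them rose and 1 or 2 fell. In the chondrogenic list 3 of 13 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.245), with CILP, a protein of cartilage matrix, 3.33-fold higher, and with 1 library left out 2 rose and 0 or 1 fell. The chondrogenic list was called higher by fry (adjusted p = 0.000668). In the osteogenic list 2 of 20 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.952). OGN, SPP1 and ALPL, the 3 that passed, had adjusted p of 0.06, 0.182 and 0.243 without CD201Low replicate 1, CD201High replicate 2 and CD201Low replicate 1. Of the 33 cell cycle genes PLK1 alone passed over all genes and over the list alone (camera adjusted p = 0.517).

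A further 5 lists were called by camera but not with an estimated correlation. In the complement list 3 of 20 rose and 2 fell, with 6 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.00392, and adjusted p = 0.216 with an estimated correlation). CLU, a secreted chaperone, was 2.66-fold higher and CFB, factor B, 2.10-fold higher, while C7, of the membrane attack complex, differed by −1.05, and 1 or 2 fell with 1 library left out. Of the 16 mesenchymal stromal surface markers 5 rose and 2 fell, with 6 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0133, and adjusted p = 0.215 with an estimated correlation), and ITGA11, a collagen receptor, was 1.81-fold higher. Without CD201High replicate 3 the list's adjusted p was 0.0741. Of 30 interferon response genes 3 rose, with 4 higher when adjusted over the list alone (camera adjusted p = 0.00114, and adjusted p = 0.205 with an estimated correlation), and of 24 cholesterol synthesis genes 2 rose and 1 fell, with 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0311, and adjusted p = 0.215 with an estimated correlation). With 1 library left out the number that rose was 1 to 3 for the stromal surface markers and 0 or 1 for the interferon and cholesterol lists, and 0 to 2 stromal surface markers and 0 cholesterol genes fell. Cholesterol synthesis lost the call without CD201High replicate 1 (0.0762), CD201High replicate 3 (0.095) or CD201Low replicate 1 (0.0505). Of 58 cytosolic ribosomal protein genes 0 passed by limma, with 0 higher and 6 lower at an unadjusted p under 0.05, and the median difference was −0.12 (camera adjusted p = 1.76e-05, and adjusted p = 0.715 with an estimated correlation).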

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

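All alternatives but that on genes above 0 in all 6 libraries were chosen before the data were examined. PROCR kept its direction under all of them, with a log2 difference of 1.81 to 1.94 when libraries were left out, and lost its call only without both libraries of number 1 (1.83, adjusted p = 0.0924) or 2 (1.83, adjusted p = 0.0734), where 2 libraries per group remained. All 571 called genes, PROCR among them, kept their direction under every alternative that tested them. With no overlap between groups, leaving out libraries could not reverse a direction. Filters and other variance models do not change the difference, so the kept directions are no separate support. The count of calls was 531 to 580 under the median shift, repeated quantile normalization, both pseudocounts, both mean filters, robust variance and genes above 0 in all 6 libraries. It moved to 118 (68 higher, 50 lower) with no variance trend, 131 (65 and 66) with no variance moderation and 963 (492 and 471) with library weights, and the cause was not tested. With 1 library left out it was 182 to 347, with 109 to 181 higher and 67 to 166 lower, and without both libraries of number 1, 2 or 3 it was 3, 2 and 157 (3, 2 and 94 higher, 0, 0 and 63 lower), from fewer samples. In the fit without number 2, 1503 genes had an unadjusted p under 0.05. Genes past an unadjusted p and 2-fold numbered 487 to 857. Camera called 13 lists, 6 with an estimated correlation, 15 with fry, 31 with fry in its mixed form, and 9 to 14 otherwise. Of 103 genes taken by the naming rule and past the test, 51 passed with any 1 library left out. Of the 103, 0 changed sign, which the lack of overlap had fixed beforehand. The labels do not say whether libraries of 1 replicate number share a donor, and the values gave no sign of it: same-numbered libraries deviated with Pearson r of 0.01, 0.01 and 0.03 across genes, not every library correlated best with its own number, and the replicate block gave 512 calls, 484 of them among the 571, and 12 lists. Camera does not use robust variance, and the fit without moderation has no list test, so lists were not run under these. Depth is unknown and sets no limit that can be given.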

Other observations

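Other fixed lists, without a camera call, still held genes that differed. Among 26 angiogenic factors 4 rose and 9 fell in CD201High (5 and 9 adjusted over the list alone, camera adjusted p = 0.332), and with 1 library left out 2 or 3 rose and 1 to 6 fell. SEMA3C, a semaphorin, was 2.27-fold higher and THBS1, which encodes thrombospondin 1, 2.38-fold higher, while THBS2 differed by −0.56. Of 14 genes of the CD142-positive stroma that regulates adipogenesis 2 rose and 4 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.532), with FMO2, a monooxygenase, differing by −1.90, and with 1 library left out 0 to 2 of the list rose and 1 to 3 fell. Of 26 hypoxia and glycolysis genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.666), the latter being ADM, the vasodilator adrenomedullin, with −1.02, and 0 to 2 rose with 1 library left out. Of 20 retinoic acid and aldehyde genes 1 rose and 2 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.161), with RARRES2, which encodes the adipokine chemerin, differing by −0.80, and with 1 library left out 0 to 2 rose and 1 or 2 fell. Fry called this list lower (adjusted p = 0.0488). Of 18 interstitial collagens 2 rose and 0 fell, over all genes and over the list alone (camera adjusted p = 0.343), namely COL14A1 (1.71-fold) and COL8A2 (1.82-fold). All genes named in this paragraph passed with any 1 library left out.

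Of 26 matrix proteases and inhibitors 3 rose and 3 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.552), and of 29 inflammatory and NF-kB genes 3 rose and 4 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.662). Of 20 Notch genes DLL1 fell (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.552), with an adjusted p of 0.118 without CD201Low replicate 1. With 1 library left out, 0 to 2 protease and inflammatory genes rose and 1 or 2 fell. Of 16 cell cycle inhibitors 2 fell (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.574), and 0 or 1 with 1 library left out. By limma 0 members passed in the lists of pluripotency factors (5 genes, camera adjusted p = 0.943), MHC class II (12, 0.175), nuclear oxidative phosphorylation (32, 0.27, and 0.0207 without CD201Low replicate 1), histones (15, 0.574), metallothioneins (7, 0.245) and HOX genes (29, 0.195). At an unadjusted p under 0.05 these lists had 1, 2, 0, 0, 3 and 1 members, and adjusted over the list alone 1 metallothionein gene was higher. The HOX list was called lower by fry (adjusted p = 0.0488). Median, mean and camera direction differed in sign for the osteogenic, chondrogenic, Wnt, TGF-beta and BMP, endothelial, mesothelial, lymphocyte, collagen, protease, inflammatory, cell cycle inhibitor and hypoxia lists.

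Of the tests below, those on ADIPOQ, on the preadipocyte list, on heat shock genes and on the ribosomal median over pairs of libraries were chosen after the result was seen, and the estimated correlation, fixed beforehand as a list test, was used to weigh the ribosomal call only then. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 571 genes, 1 of 10 splits gave as many, and the highest of the others called 0.

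The mature adipocyte list was called lower in CD201High libraries, with a median difference of −1.02 and all 16 members lower in mean, ADIPOQ among them, though 10 did not pass. A larger share of mature adipocytes, or their free RNA, in the CD201Low sort would bring ADIPOQ, among the most abundant adipocyte transcripts, at least as strongly as GPD1. On the linear scale the rise of ADIPOQ from CD201High to CD201Low was 1.00% of that of GPD1, and at most 14.4% over pairs of libraries. ADIPOQ thus did not match the rise of GPD1. The comparison rests on a single gene that varied widely in CD201High. It also sets linear amounts of different genes side by side, while the absolute scale is unclear. It therefore does not decide on that source for the list. The committed preadipocyte list, which shares no gene with the mature adipocyte list, was called lower too (median difference −0.49). That call is a result already given, so it is no separate support for preadipocytes further along adipogenesis among CD201Low cells. Both explanations stay open.

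Immediate early genes were lower in CD201High libraries, with a median difference of −0.22. The lower quartile of the heat shock members was −0.11. Heat shock genes as a set thus did not move as much as immediate early genes. This comparison was chosen after the result was seen, so it is no separate test of a stronger stress response in the CD201Low sort. A smaller move of heat shock genes is not excluded, since 8 of 21 were higher in mean in CD201High and the others were not. The third CD201High library, which stood apart, does not account for the immediate early result alone, since that list was called lower without it (camera adjusted p = 1.88e-10). A stimulus that spares heat shock genes or moves them less, the order or time of sorting, and a difference between the CD201 classes themselves were not tested and stay open.

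Ribosomal protein genes lay lower in CD201High libraries, with a median difference of −0.12. A trend with transcript length and mean value gave a median of −0.03 in 10000 matched random sets of 58 genes, and the observed median lay at percentile 0.05. Random sets do not move together as these genes do, and over pairs of libraries the ribosomal median ran from −0.35 to 0.17, so this trend stays open. Swings between libraries that these genes share may account for the call, since it ended with the estimated correlation of 0.816 (adjusted p = 0.715). A biological difference between the CD201 classes stays open and was not tested further.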
